A study of Caenorhabditis elegans with 12 samples.

How the data were processed

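The series holds RNA sequencing of whole worms in 12 libraries, 1 per combination of genotype and temperature. Libraries were assigned to groups from the genotype and temperature labels. For 3 libraries grown at 20 °C the title names ung-1 where the genotype label names nth-1, and the genotype label was used. Each deposited file gave 1 read count per gene, as whole numbers with different totals per library, so the counts were taken as not normalised. Reads were aligned with HISAT2 against the WBcel235 genome, and edgeR 3.22.5 was used by the authors, per the submitters' processing notes. The aligner's version, the counting program, its use of strand, its handling of reads that match several places and the annotation are not given in the sources used here. Without that, genes that overlap on the same or on opposite strands, and members of families with near-identical copies such as the fbxa, bath, msp, vit, clec and hsp-16 genes, may share reads, and their single values are uncertain. The same holds for a pseudogene and its parent gene.

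The files held 46589 genes. Of these, 46180 identifiers matched the Ensembl 115 annotation of the same build, which gave names, biotypes and coordinates, and 11393 had a name other than a clone name. Unmatched identifiers took 0.228% of the counts summed over all libraries. Library totals ran from 15124127 to 35204808 counts, and the ribosomal RNA share from 0.082% to 1.034%. The closest libraries, nth-1 and nth-1 with aggregate tau, differed over 4160 genes with a variance 6.7 times that of counting noise, which does not by itself show separate samples, and each library was used as the single member of the group its labels give.

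Counts were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test, after TMM scaling and the default filter on low counts, which kept 15245 genes, with Benjamini-Hochberg adjustment at 0.05. Background and tau state entered 1 fit of the 12 libraries, with 6 residual degrees of freedom, for the 3 contrasts of tau states, the 2 mutants, their difference and the 2 temperatures. A fit with a term for loss of either glycosylase by tau state, with 4 residual degrees of freedom, served for loss of a glycosylase within the aggregate strain and for its interaction with aggregate tau. The contrasts on wild-type backgrounds were taken from this fit as well, so their spread also came from all 12 libraries. The residual spread is the interaction of background and tau state together with the noise of single libraries. Log2 ratios of single libraries used TMM-normalised CPM with a prior count of 2, and their 95% intervals are exact Poisson intervals of the counts.

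Gene lists for pathways, tissues and stages, 42 in number, were fixed with the groups, the tests and the alternatives before the data were examined, and 41 had at least 3 measured members; the list of mitochondrially encoded genes matched 0 names and was not tested. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01. With a correlation estimated from the residuals none of the camera calls held in any of the 9 planned comparisons. Fry of limma, which asks whether the members of a list move on balance, was run beside it. Members past the threshold were counted over all genes and also adjusted over the list alone. In single-library pairs, of which 19 were read, a list's median was placed among 10000 random lists of the same size drawn from 20 bins of mean expression among genes with a mean of at least 1 CPM, and correlations used genes with a mean of at least 5 CPM.

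Genes were named by a fixed rule: among genes past the threshold with a mean of at least 5 CPM, a gene name other than a clone name and the same direction in each matched pair, the 12 largest changes each way. Where none passed, the 5 genes with the smallest p each way were given as values, and within each list up to 4 members past the threshold. For the mutant aggregate over aggregate pairs the 5 largest changes each way were named. A gene chosen after its values were seen is said to be so.

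The alternatives tried were other size factors, no filter and a stricter filter, DESeq2 1.42.0, limma voom, other libraries or covariates in the fit, leaving out the germline, sperm, oocyte, embryo, vitellogenin, collagen and moulting genes, and leaving out each library. Contrasts on wild-type backgrounds, fits without the 3 nth-1 libraries and readings without the genes called on wild-type backgrounds were added after the data were seen. Counts were first simulated with dispersions, the spread beyond counting, fitted to the data by background and tau state (median 0.165). For the tau aggregate comparison with 14797 genes, 200 of them changed, the edgeR test recovered 38% of the 2-fold and 77% of the 4-fold changes with 6 false calls. For the nth-1 comparison it recovered 21% and 67% over 14784 genes, for loss of a glycosylase in the aggregate strain 2% and 47%, and for the interaction 0% and 0%, both over 14813 genes. DESeq2 made 81, 86, 92 and 95 false calls in the same 4 simulations. Recovery depended on the dispersion. At a dispersion of 0.02 edgeR recovered 85% and 100% for loss of a glycosylase in the aggregate strain and 44% and 100% for the interaction. It recovered 100% and 100% for the tau aggregate comparison and 98% and 100% for nth-1, and DESeq2 made 26, 25, 8 and 14 false calls. The simulated genes were drawn independently of each other, with no shift shared by many genes of a library. The rates of recovery and of false calls hold for that setting, and the libraries here do hold such shifts. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.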

Results

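Gene expression was measured by RNA sequencing of whole Caenorhabditis elegans at day 1 of adulthood, in 12 libraries of about 5000 worms each, grown on 3 plates per strain. Each of 4 backgrounds held 3 tau states: no tau, the tau aggregate strain BR5270 and the anti-aggregate strain BR5271. BR5270 expresses in its neurons a fragment of human tau that is prone to aggregate, and BR5271 the same fragment altered so that it resists aggregation. The backgrounds were wild type (N2) and ung-1 mutants at 22 °C, and wild type and nth-1 mutants at 20 °C. UNG-1 is a uracil-DNA glycosylase and NTH-1 removes oxidised pyrimidines, so both act at the start of base excision repair. Each combination of genotype and temperature had 1 library. With no replicate of a combination, the p-values rest on the interaction of background and tau state together with the noise of single libraries. How far replicate cultures of 1 strain would differ was not measured. At 22 °C the deposited counts summed to 24342707 in the wild type, 19791392 with aggregate tau, 21683203 with anti-aggregate tau, 35204808 in ung-1, 21953573 in ung-1 with aggregate tau and 18594381 in ung-1 with anti-aggregate tau. At 20 °C they summed to 26282132, 15124127 and 17346213 on the wild-type background and to 22726011, 16393122 and 22640446 on the nth-1 background, in the same order. Temperature, set of libraries and mutated gene changed together, so an ung-1 effect and an nth-1 effect were measured at different temperatures. Counting intervals cover counting error only.

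The targeted genes were read first in every library. The ung-1 gene (III, 11971467 to 11974096, minus strand) lay at 14.01 CPM (95% counting interval 12.8 to 15.3) in the ung-1 library. It lay at 14.4 with aggregate tau and at 11.8 with anti-aggregate tau on that background, against 45.3, 41.2 and 46.7 in the matching wild-type libraries. At 20 °C ung-1 was at 58.0 CPM in the wild type, 39.3 and 59.0 with aggregate and anti-aggregate tau on the wild-type background, 28 in the nth-1 library, 29.6 in nth-1 with aggregate tau and 49.03 in the library labelled nth-1 with anti-aggregate tau. The nth-1 gene (III, 4291543 to 4294253, minus strand) lay at 5.24 CPM (4.32 to 6.31) in the nth-1 library and 5.38 (4.28 to 6.67) in nth-1 with aggregate tau. The 3 libraries of wild-type background at 20 °C held 24.6, 23.9 and 25.3 CPM. In the library labelled nth-1 with anti-aggregate tau it reached 11.2 CPM (9.85 to 12.7), between the mutant and the wild-type levels, so this library partly went against its label. At 22 °C nth-1 lay between 24.6 and 30.7 CPM.

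**Figure D1:**
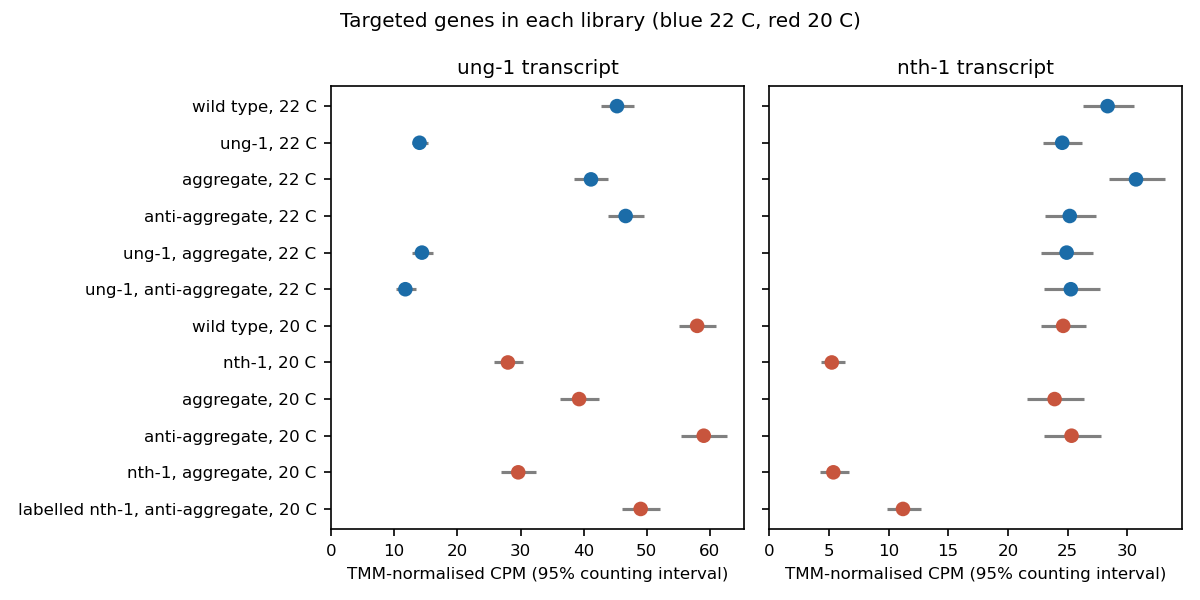
Normalised CPM of ung-1 (left) and nth-1 (right) in each of the 12 libraries, with 95% counting intervals as bars, where blue points are the 22 °C libraries and red points the 20 °C libraries. The 3 ung-1 libraries sit between 11.8 and 14.4 CPM of ung-1, and the library labelled nth-1 with anti-aggregate tau sits at 11.2 CPM of nth-1, above the 5.24 and 5.38 of the other nth-1 libraries.

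The comparison of mutants with wild type within the tau aggregate strain asked what loss of a glycosylase does to expression in worms with aggregating tau. Over the 2 mutations together 149 genes fell and 1 gene, smg-3, rose (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05 over 15245 genes, 2 libraries against 2, 1 pair per temperature). The gene smg-3 (IV, 6362395 to 6373093), whose product acts in nonsense-mediated mRNA decay, rose by a log2 fold change of 1.64 (SE 0.19, adjusted p = 0.0147). It went from 32.9 CPM at 22 °C and 49.98 CPM at 20 °C in the aggregate libraries to 153 CPM with ung-1 loss and 100.4 CPM with nth-1 loss. Among the genes that fell was odc-1 (V, 6898540 to 6900223), encoding ornithine decarboxylase, the entry enzyme of polyamine synthesis, with a log2 fold change of -4.21 (SE 0.24, adjusted p = 0.00314). Its level was 523 and 465 CPM in the 2 aggregate libraries and 19.8 and 35.2 CPM in the matching mutants. Without tau, smg-3 stood at 135 and 158 CPM in the wild types of 22 °C and 20 °C, 129 in ung-1 and 108 in nth-1. In the same order odc-1 stood at 19, 12.8, 22.0 and 34.1 CPM. For both genes the mutant aggregate libraries thus lay near the libraries without tau, and the aggregate libraries on wild type lay apart. Among genes with a name other than a clone name and a mean of at least 5 CPM, the largest falls were those of the astacin protease gene nas-21 (-5.11, SE 0.77) and the cyclic nucleotide-gated channel gene cng-1 (-4.86, SE 0.65). Also lower were ift-43, for intraflagellar transport (-3.76, SE 0.23), the acyl-CoA dehydrogenase gene acdh-2 (-3.46, SE 0.44), lir-2 (-3.15, SE 0.28) and the long non-coding RNAs linc-20 (-3.93, SE 0.43) and linc-9 (-3.42, SE 0.36). Their adjusted p-values ran from 0.00344 for ift-43 to 0.0354 for nas-21. Genes were named only if they moved the same way in both pairs.

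By gene list, 4 of 202 measured genes of the F-box, MATH and BATH families fell within the aggregate strain and none rose: fbxa-94 (-3.84, SE 0.63), fbxa-140 (-3.80, SE 0.33), fbxa-209 (-3.56, SE 0.55) and fbxa-211 (-3.55, SE 0.28). Adjusted over the list alone 5 fell. The list as a whole lay lower by camera (median -0.26, adjusted p = 0.0127), with adjusted p = 0.929 with an estimated correlation. The 84 cytosolic ribosomal protein genes went apart: 71 had a positive log2 fold change and the list median was 0.31 (camera adjusted p = 1.33e-07, and adjusted p = 0.989 with an estimated correlation). Against that median rpl-30 fell (-1.08, SE 0.16, adjusted p = 0.0322), and 5 fell adjusted over the list alone. Of 33 proteasome genes, rpn-6.2 fell (-2.29, SE 0.22, adjusted p = 0.0112). Of 62 sperm development genes spe-44, a regulator of sperm genes, fell (-1.58, SE 0.22, adjusted p = 0.0279). For cytosolic heat shock 20 of 22 members had positive values, with a median of 0.75 and none past the threshold. Its camera adjusted p was 4.12e-06, with adjusted p = 0.501 with an estimated correlation. The 6 vitellogenins, yolk proteins made in the intestine, had a median of 0.81 (camera adjusted p = 0.00242, and adjusted p = 0.929 with an estimated correlation). Of 137 cuticle collagens 33 had positive values (median -0.50, camera adjusted p = 0.0127, and adjusted p = 0.989 with an estimated correlation). This pooled collagen median covers an ung-1 pair and an nth-1 pair that went opposite ways, as the single libraries below show. The pooled vitellogenin median came largely from the 22 °C pair, where the members lay from -2.18 to -0.59 over wild type in the aggregate library. At 20 °C they ran from -0.413 to 0.798 over wild type in the aggregate library and from -0.411 to 0.805 in nth-1 with aggregate tau. Annotated pseudogenes made up 32.2% of the genes that fell (48 of 149), against 4.15% of the genes tested (633 of 15245). Scaling by total counts in place of TMM moved the median of all tested genes in this comparison from 0.004 to -0.231, and the ribosomal median to 0.07.

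The number of genes called within the aggregate strain was 648 by DESeq2 and 295 by limma voom, and 1580 had an unadjusted p under 0.05 where chance gives 762. It moved with each library left out. It was 0 without the ung-1 aggregate or the nth-1 aggregate library, 2 and 1 without the aggregate library of 22 °C and of 20 °C, 41 and 42 without the wild type, 28 and 74 without ung-1 and nth-1, and 67 and 66 without the anti-aggregate library. It was 478 without ung-1 with anti-aggregate tau and 451 without the library labelled nth-1 with anti-aggregate tau. Over 18 alternatives the adjusted p of smg-3 ran from 6.63e-11 to 0.31 and passed in 10, and that of odc-1 ran from 1.93e-63 to 0.0612 and passed in 15.

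**Figure D2:**
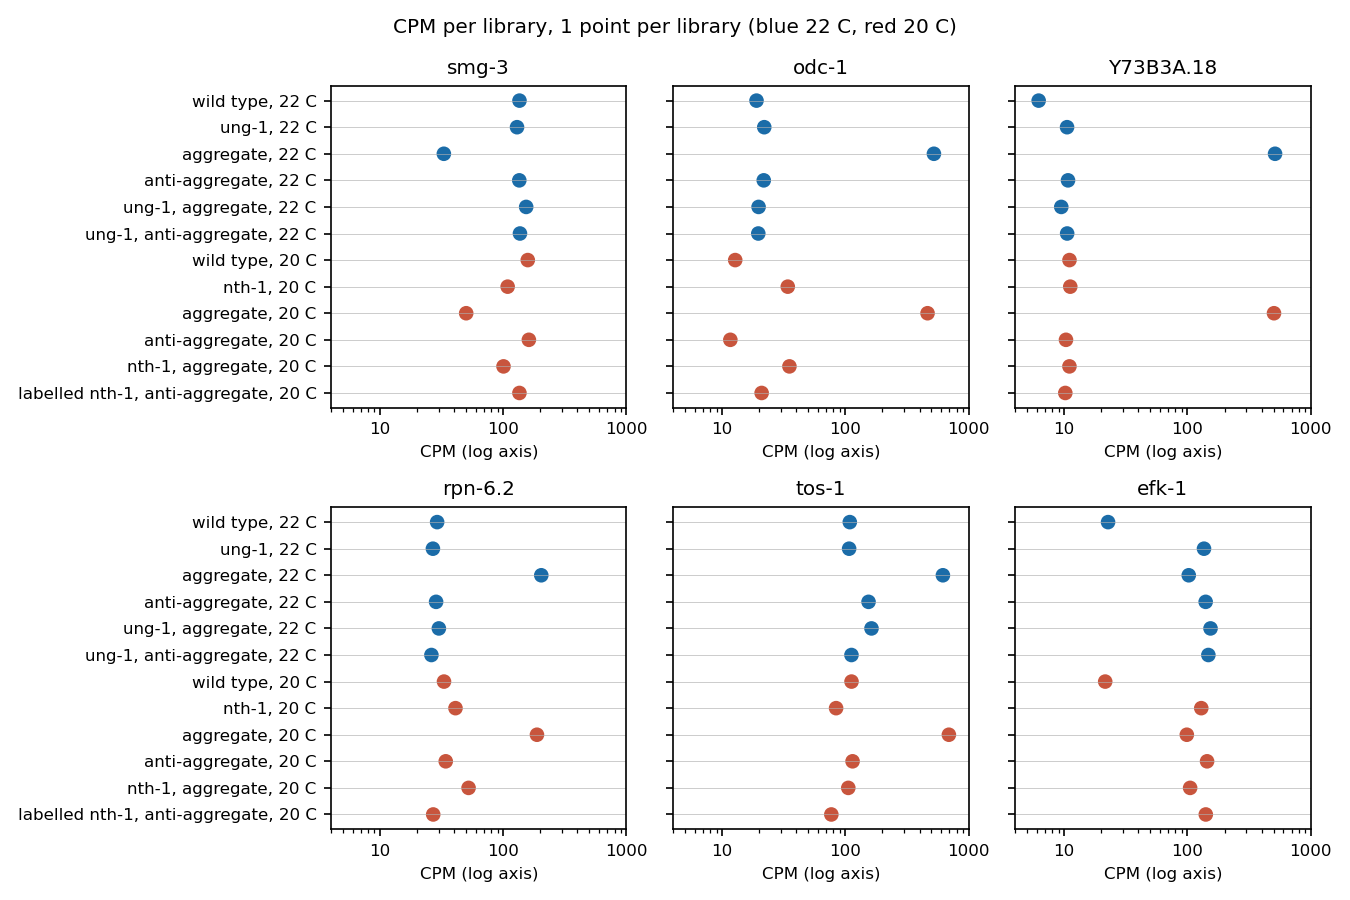
CPM on a log axis of smg-3, odc-1, Y73B3A.18, rpn-6.2, tos-1 and efk-1 in each of the 12 libraries, 1 point per library, blue at 22 °C and red at 20 °C. The 2 aggregate libraries on a wild-type background hold 32.9 and 49.98 CPM of smg-3 against 100.4 to 161 in the other 10, and 523 and 465 CPM of odc-1 against 11.7 to 35.2, while efk-1 is lowest in the 2 wild-type libraries without tau.

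Whether the aggregate effect differed between wild-type and glycosylase-mutant backgrounds was tested as an interaction, and it differed for 2 genes. For odc-1 the aggregate effect was lower in the mutants by a log2 difference of -4.95 (SE 0.32). For Y73B3A.18 (X, 59366 to 60750), a pseudogene with a clone name that was chosen after its value was seen, the difference was -5.91 (SE 0.36), and both had an edgeR quasi-likelihood adjusted p of 0.00693. No other gene of the 15245 tested passed, with 1783 at an unadjusted p under 0.05. Cuticle collagens had negative interaction values in 134 of 137 members (median -2.99, camera adjusted p = 1.95e-07, and adjusted p = 0.666 with an estimated correlation). So did 60 of 62 sperm development genes (median -3.03, camera adjusted p = 0.00108, and adjusted p = 0.671 with an estimated correlation) and 31 of 33 muscle genes (median -1.30, camera adjusted p = 0.00108; adjusted p = 0.666 with an estimated correlation). All 29 germline and meiosis genes had positive values (median 0.45, camera adjusted p = 4.92e-07; adjusted p = 0.666 with an estimated correlation). Adjusted over the list alone 1 muscle gene and no collagen, sperm or germline gene passed. The median of all genes was -0.33 with TMM and -0.59 with total counts. Without the 3 nth-1 libraries 131 genes differed. DESeq2 called 385 genes and voom 28. Leaving out 1 library gave 0 genes called without ung-1, nth-1, either aggregate library or either mutant aggregate library, 2 without either anti-aggregate library on a wild-type background and 1 without either wild type. It gave 163 without ung-1 with anti-aggregate tau and 152 without the library labelled nth-1 with anti-aggregate tau.

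Tau aggregate against no tau, over the 4 backgrounds, asked what the aggregating tau changes whatever the background. Among the genes with the smallest p were xbp-1, the transcription factor of the unfolded protein response (log2 fold change 0.82, SE 0.17), the lysozyme gene lys-7 (1.71, SE 0.42), vmo-1 (2.69, SE 0.65), fbxa-189 (2.1, SE 0.51) and lact-3 (1.15, SE 0.29). On the negative side stood nrd-1 (-0.49, SE 0.12), the RNA-directed RNA polymerase gene rrf-1 (-0.56, SE 0.14), rpc-1 (-0.48, SE 0.12), the nuclear envelope gene lem-2 (-0.61, SE 0.16) and rig-4 (-0.57, SE 0.15). None of these 10 passed (edgeR quasi-likelihood adjusted p = 0.363 for each, 4 libraries against 4). All 29 germline and meiosis genes had negative values (median -0.34, camera adjusted p = 1.95e-09), and so had all 28 oocyte and eggshell genes (median -0.43, 7.98e-09). By contrast 127 of 137 collagens (median 1.48, 6.37e-06) and 108 of 117 C-type lectins, often induced by infection (median 1.07, 1.09e-07), had positive ones. Each of these 4 lists had adjusted p = 0.729 with an estimated correlation. Their values average over backgrounds that differed, and do not show a change whatever the background. On wild-type backgrounds the medians were -0.58 for germline, -0.66 for oocyte, 3.13 for collagen and 1.97 for lectin genes. The interaction with glycosylase loss had medians of the opposite sign, at 0.45, 0.45, -2.99 and -1.60 in the same order. In total 24 of 41 lists passed camera, and adjusted over the list alone no gene of the 4 lists passed. By edgeR 0 genes passed, with 1874 at an unadjusted p under 0.05, 57 called by DESeq2 and 0 by voom. In the 20 °C set alone 59 passed, 58 higher and 1 lower, and in the 22 °C set alone 0, with 980 at an unadjusted p under 0.05.

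On wild-type backgrounds, a comparison chosen after the data were seen, aggregate tau was read in 2 libraries against 2. The contrast was taken from the interaction fit of all 12 libraries, so its spread came from the mutant and anti-aggregate libraries as well. In it 227 genes rose and 3 fell. The 3 that fell were smg-3 (-1.96, SE 0.19, edgeR quasi-likelihood adjusted p = 0.011), clu-1 (-0.94, SE 0.17, adjusted p = 0.0486) and T28D9.1 (-0.70, SE 0.12, adjusted p = 0.0467), the last of them chosen after its value was seen. Of the 227 that rose, 129 were among the 149 that fell with glycosylase loss within the aggregate strain, a comparison that uses the same 2 aggregate libraries. Rises included odc-1 (4.88, SE 0.25, adjusted p = 0.0014), dyla-1 (5.76, SE 0.94), nas-21 (5.32, SE 0.77), cng-1 (4.90, SE 0.64), the lectin gene clec-165 (4.66, SE 0.70), the glutamate receptor gene glr-6 (3.69, SE 0.37) and the glutathione peroxidase gene gpx-4 (3.63, SE 0.58), with adjusted p between 0.0118 and 0.0427 for the last 6. The splicing reporter gene tos-1, whose spliced forms include decay targets, stood at 619 and 692 CPM in the aggregate libraries and at 76.9 to 163 CPM in the other 10 (log2 fold change 2.46, SE 0.18, adjusted p = 0.00534). It was chosen after its values were seen. Of the C-type lectins 3 of 117 rose (clec-75 by 6.66, SE 0.95, clec-165, and clec-180 by 4.14, SE 0.68; 12 adjusted over the list alone). Of the F-box, MATH and BATH families 6 of 202 rose (10 adjusted over the list alone). Of the ribosomal protein genes 4 of 84 rose (ubl-1 1.06, rpl-7A 1.01, rps-22 1.01, rpl-30 0.89, with SE 0.15 to 0.17; 5 adjusted over the list alone). That list's median was -0.30 (camera adjusted p = 4.47e-06; adjusted p = 0.664 with an estimated correlation). The proteasome gene rpn-6.2 also rose (2.55, SE 0.23, adjusted p = 0.0091) in a list with a median of -0.48 (camera adjusted p = 2.84e-07; adjusted p = 0.664 with an estimated correlation). Collagens had positive values in 133 of 137 members (median 3.13) with none past the threshold, also adjusted over the list alone (camera adjusted p = 2.34e-07, and adjusted p = 0.664 with an estimated correlation). In the germline and meiosis list 16 genes fell adjusted over the list alone (median of the 29 members -0.58, camera adjusted p = 4.06e-09; adjusted p = 0.664 with an estimated correlation). Pseudogenes were 29.1% of the genes that rose (66 of 227). The median of all genes was 0.46 with TMM and 0.67 with total counts.

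The count of 230 genes on wild-type backgrounds became 3304 by DESeq2, 778 by voom and 3616 without the 3 nth-1 libraries. With 1 library left out it was 1 without either wild type, 2 without either aggregate library, 42 without ung-1, 64 without nth-1, 80 and 82 without the anti-aggregate libraries of 22 °C and 20 °C, and 79 and 139 without the aggregate libraries of ung-1 and nth-1. It was 5671 without ung-1 with anti-aggregate tau and 5645 without the library labelled nth-1 with anti-aggregate tau.

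Anti-aggregate tau against no tau gave values for the neighbouring genes bath-28 (II, 3343731 to 3344967; log2 fold change 0.82, SE 0.17) and bath-30 (II, 3345218 to 3346378; 0.73, SE 0.17), and the thaumatin family gene thn-2 (0.78, SE 0.25). Negative values were those of sbsp-1 (-1.33, SE 0.41), the galectin gene lec-5 (-0.46, SE 0.15) and kynu-1, for kynureninase (-0.78, SE 0.29). None of these passed (edgeR quasi-likelihood adjusted p = 0.997 for each, 4 libraries against 4). Cuticle collagens had negative values in 120 of 137 members (median -0.66, camera adjusted p = 1.79e-07; adjusted p = 0.869 with an estimated correlation; 0 adjusted over the list alone). Between single libraries the collagen median went both ways with anti-aggregate tau: 0.99 and -0.67 on the wild-type backgrounds of 22 °C and 20 °C, 0.10 on ung-1 and -4.22 in the library labelled nth-1 with anti-aggregate tau. In the list of endoplasmic reticulum stress 19 of 20 genes had positive values (median 0.15, camera adjusted p = 1.39e-05; adjusted p = 0.869 with an estimated correlation; 0 adjusted over the list alone). By edgeR 0 genes passed, with 253 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by voom. In the 20 °C set, which holds the library labelled nth-1 with anti-aggregate tau, 1489 passed, 28 higher and 1461 lower, and in the 22 °C set 0, with 277 at an unadjusted p under 0.05. On wild-type backgrounds, read after the data were seen, 1 gene rose: efk-1 (III, 6164906 to 6168547), for the kinase of elongation factor eEF2 (2.67, SE 0.18, adjusted p = 0.0223). Its level was 22.7 and 21.5 CPM in the 2 wild-type libraries without tau and 98.8 to 154 CPM in the other 10.

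Aggregate against anti-aggregate tau compared the strains that differ in whether the tau fragment can aggregate. On wild-type backgrounds 145 genes were higher and 4 lower with aggregates, 2 libraries against 2, in a comparison chosen after the data were seen. The highest were cng-1 (5.66, SE 0.68), nas-21 (5.42, SE 0.77), clec-165 (5.12, SE 0.72) and odc-1 (4.86, SE 0.25). The 4 lower were smg-3 (-1.95, SE 0.19), bath-30 (-1.35, SE 0.20), bath-28 (-1.31, SE 0.21) and the arrestin-domain gene arrd-13 (-1.26, SE 0.20), with edgeR quasi-likelihood adjusted p from 0.00153 for odc-1 to 0.0468 for bath-28. Over all 4 backgrounds the kinase gene unc-82, of muscle, had a log2 fold change of 1.5 (SE 0.38), fbxa-69 of 1.83 (SE 0.46) and alh-6 of 0.85 (SE 0.23). The linker histone genes hil-2 and hil-5 had log2 fold changes of -0.92 (SE 0.19) and -0.57 (SE 0.12), and none of these 5 passed (adjusted p = 0.137). All 28 oocyte and eggshell genes had negative values (median -0.66, camera adjusted p = 9.06e-11; adjusted p = 0.664 with an estimated correlation), and adjusted over the list alone 25 fell. Adjusted over the list alone, 16 of 29 DNA damage response genes fell (median -0.46, camera adjusted p = 1.13e-09), 9 of 14 base excision repair genes fell (median -0.53, 5.02e-05) and 11 of 33 muscle genes rose (median 0.98, 6.03e-05). Each of these 3 lists had adjusted p = 0.664 with an estimated correlation. These values and those of the oocyte list also take in the library labelled nth-1 with anti-aggregate tau. Between nth-1 with aggregate tau and that library, unc-54 of muscle stood at 4081 against 674 CPM. In the same pair nth-1 stood at 5.38 against 11.2 CPM and ung-1 at 29.6 against 49.03, and both belong to the base excision repair list. Over all genes tested edgeR passed 0, with 5047 at an unadjusted p under 0.05, 1153 by DESeq2 and 0 by voom, and the 20 °C set alone, which holds the library labelled nth-1 with anti-aggregate tau, passed 4507. The 22 °C set alone passed 0, with 152 at an unadjusted p under 0.05.

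Loss of ung-1 was read in 3 libraries against 3 at 22 °C. The small heat shock gene hsp-16.2 had a log2 fold change of 2.86 (SE 0.68), the fatty acid elongase gene elo-6 of 0.69 (SE 0.14), nhr-17 of 1.5 (SE 0.32), epn-1 of 0.58 (SE 0.14) and pqn-65 of 0.90 (SE 0.26). On the other side were ung-1 itself (-1.69, SE 0.27), sop-2 (-1.21, SE 0.31), nhr-47 (-1.02, SE 0.27), tmem-132 (-1.90, SE 0.51) and the homeobox gene ceh-20 (-1.16, SE 0.40). None of the 10 passed (edgeR quasi-likelihood adjusted p = 1 for each). Of the cytosolic heat shock list 20 of 22 members had positive values (median 0.36, camera adjusted p = 2.81e-12; adjusted p = 0.0645 with an estimated correlation; 1 higher adjusted over the list alone). Of the collagens 118 of 137 had negative ones (median -0.53, camera adjusted p = 4.55e-06; adjusted p = 0.999 with an estimated correlation; 0 adjusted over the list alone). All 6 vitellogenins had positive values (median 0.57, camera adjusted p = 8.03e-06; adjusted p = 0.769 with an estimated correlation; 0 adjusted over the list alone). These list values average the tau states. They take in the aggregate library on wild type, which had high collagens and low vitellogenins, as the single libraries below show. The collagen gene col-19, chosen after its values were seen, stood at 419 CPM in ung-1 against 207 in the wild type. With aggregate tau it stood at 357 against 1763 CPM, and with anti-aggregate tau at 421 against 481. By edgeR 0 genes passed, with 160 at an unadjusted p under 0.05, 5 by DESeq2 and 0 by voom.

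Loss of nth-1 was read in 3 libraries against 3 at 20 °C, 1 of them the library labelled nth-1 with anti-aggregate tau. The values included hsp-16.2 (4.22, SE 0.72), unc-23, a chaperone regulator in muscle (2.31, SE 0.37), the fumarase gene fum-1 (0.74, SE 0.11), gsk-3, a tau kinase (0.73, SE 0.11), and nuo-5 of respiratory complex I (0.69, SE 0.12). Negative values were those of nth-1 (-1.87, SE 0.31), the RNA ligase gene rtcb-1 (-1.49, SE 0.19), sorf-2 (-1.44, SE 0.20), damt-1 (-1.33, SE 0.22) and bath-28 (-1.26, SE 0.20). None of the 10 passed (edgeR quasi-likelihood adjusted p = 0.0692 for each). Adjusted over the list alone, 32 of 33 muscle genes rose (median 1.61, camera adjusted p = 1.57e-08), and 10 of 22 cytosolic heat shock genes rose and 2 fell (median 1.25, 0.00146). Likewise 11 of 29 DNA damage response genes fell (median -0.41, 6.55e-05) and 7 of 14 base excision repair genes fell (median -0.63, 0.000104). Each of these 4 lists had adjusted p = 0.923 with an estimated correlation. Medians were also negative for early embryo zygotic genes (-1.05), replicative histones (-0.71), oocyte and eggshell genes (-0.30) and germline and meiosis genes (-0.05). All 30 major sperm protein genes had positive values (median 3.89, camera adjusted p = 0.000246; adjusted p = 0.923 with an estimated correlation; 0 adjusted over the list alone). Of the tau kinases and modifiers 5 of 15 rose and 2 fell adjusted over the list alone, with a fry adjusted p of 0.000741 and a camera adjusted p of 0.286. By edgeR 0 genes passed, with 5575 at an unadjusted p under 0.05, 4210 by DESeq2 and 1386 by voom. Without the library labelled nth-1 with anti-aggregate tau 5318 genes passed, without the ung-1 aggregate library 1535, and with the 20 °C libraries alone 3463.

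The test of the difference between the ung-1 and nth-1 effects, which also rests on the library labelled nth-1 with anti-aggregate tau, gave positive values for rtcb-1 (1.35, SE 0.26), the lysozyme gene lys-10 (3.71, SE 0.72) and sorf-2 (1.44, SE 0.28). It gave negative ones for the phosphofructokinase gene pfk-1.1 (-0.94, SE 0.22), fum-1 (-0.63, SE 0.15) and spe-15 (-3.67, SE 0.89), and none of the 6 passed (edgeR quasi-likelihood adjusted p = 0.259 for each). The muscle list had a median of -1.63, and 19 of 33 fell adjusted over the list alone (camera adjusted p = 1.79e-08; adjusted p = 0.833 with an estimated correlation). The collagen median was -2.91 with 125 of 137 negative (camera adjusted p = 1.38e-07; adjusted p = 0.833 with an estimated correlation; 0 adjusted over the list alone). By edgeR 0 genes passed, with 2806 at an unadjusted p under 0.05, 74 by DESeq2 and 0 by voom, and 953 passed without the library labelled nth-1 with anti-aggregate tau.

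The wild-type background at 22 °C was set against that at 20 °C in 3 libraries each, a split that is also the split between the sets. The values were positive for pud-4 (5.91, SE 0.95), sysm-1 (3.81, SE 0.57), fbxb-97 (3.08, SE 0.45), sop-2 (2.32, SE 0.32) and the synaptotagmin gene snt-2 (1.54, SE 0.24), with an adjusted p of 0.359 for each. They were negative for the fatty acid desaturase gene fat-7 (-1.78, SE 0.42), his-67 (-1.67, SE 0.39), rbm-3.1 (-1.02, SE 0.19), sec-61.G (-0.63, SE 0.15) and the fibrillarin gene fib-1 (-0.49, SE 0.12). None passed, and the edgeR quasi-likelihood adjusted p of these 5 was 0.521 to 0.523. Ribosomal protein genes had negative values in 79 of 84 members (median -0.31, camera adjusted p = 1.01e-16; adjusted p = 0.902 with an estimated correlation; 0 adjusted over the list alone). Cytochrome P450 genes, of detoxification, had positive values in 50 of 60 (median 0.79, camera adjusted p = 1.78e-06; adjusted p = 0.902 with an estimated correlation; 1 higher adjusted over the list alone). Of the 6 vitellogenins 3 rose adjusted over the list alone (median 0.69, camera adjusted p = 0.0139; adjusted p = 0.902 with an estimated correlation). By edgeR 0 genes passed, with 1147 at an unadjusted p under 0.05, 125 by DESeq2 and 0 by voom. Without the library labelled nth-1 with anti-aggregate tau 2 passed, and 1 without ung-1.

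Single libraries were compared within each temperature, with no replicate check and hence no p-value across genes. A gene was counted when it differed by a log2 ratio of at least 1 and reached 10 CPM in the higher library. With aggregate tau on a wild-type background 1218 genes were higher and 90 lower at 22 °C (1437 and 59 with total counts), and 1684 higher and 34 lower at 20 °C (1837 and 12). On the ung-1 background aggregate tau gave 335 higher and 137 lower (247 and 184 with total counts), and on the nth-1 background 21 and 13. Collagens had a median log2 ratio of 2.84 at 22 °C and 2.94 at 20 °C with aggregate tau on wild type (each at percentile 100 among 10000 random lists matched on mean expression), and -0.23 and 0.34 on the ung-1 and nth-1 backgrounds. Body wall and pharyngeal muscle genes had medians of 1.20 and 1.51, neuropeptides 1.63 and 2.07, and oocyte and eggshell genes -0.54 and -0.53 (percentile 0 for both) on wild type. The vitellogenins parted, at -1.47 at 22 °C (percentile 0) and 0.02 at 20 °C (percentile 86.9). The nth-1 library over its wild type held 2518 genes higher and 1066 lower (2297 and 1508 with total counts), with collagens at 3.81, muscle at 2.67 and cytosolic heat shock at 2.04 (percentile 99.99). The ung-1 library over its own held 173 and 22. The library labelled nth-1 with anti-aggregate tau had 284 genes higher and 2165 lower than the nth-1 library, with muscle at -1.83. It had 238 higher and 60 lower than the anti-aggregate library (216 and 87 with total counts). The nth-1 transcript of this library stood between mutant and wild-type levels, which bears on both of these directions. Scaling by total counts moved the median of all genes by 0.14 in the aggregate over wild-type pair of 22 °C, by -0.16 in the nth-1 over wild-type pair and by -0.13 in aggregate tau on ung-1.

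**Figure D3:**
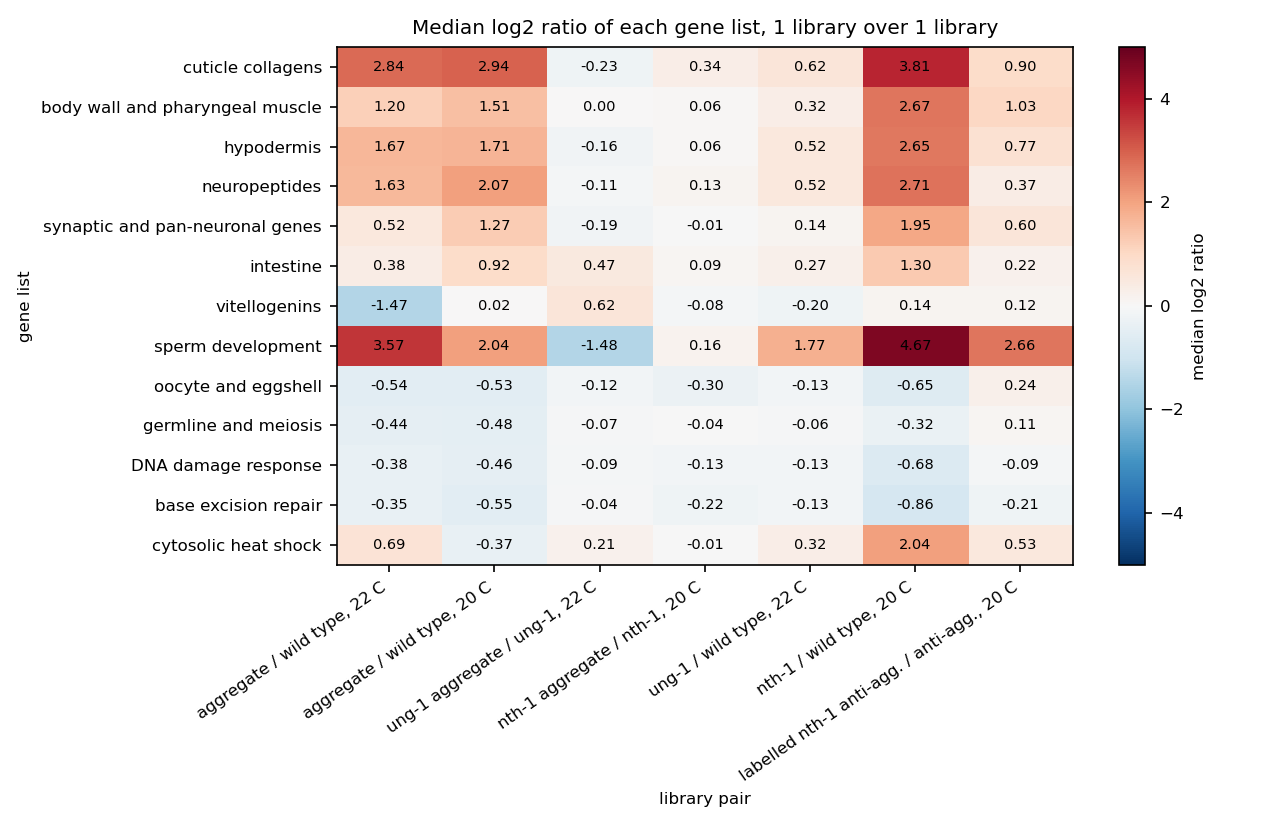
Median log2 ratio of 13 gene lists (vertical axis) in 7 pairs of single libraries (horizontal axis), coloured from blue (lower in the first library) to red (higher), with each median printed. Collagens reach 2.84 and 2.94 in the aggregate over wild-type pairs and 3.81 in the nth-1 over wild-type pair, against -0.23 and 0.34 where aggregate tau is read on the mutant backgrounds.

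With ung-1 loss in the aggregate strain, 280 genes were higher and 927 lower at 22 °C (163 and 1163 with total counts). The metallothionein gene mtl-1 stood at 28.97 CPM (26.7 to 31.4) against 2.96 (2.28 to 3.77), the non-coding RNA tts-1 at 844 against 108, the ferritin gene ftn-1 at 14.8 against 2.0, and cyp-37B1 and cyp-13A5 had log2 ratios of 2.93 and 2.84. Among the lower genes were bli-6 (1 count against 353), nas-21 (0.29 against 33.8 CPM), nspd-5 (2 counts against 276), cng-1 (1.11 against 77.5 CPM) and msp-40 (5 counts against 403). With nth-1 loss in the aggregate strain, 1534 genes were higher and 739 lower at 20 °C (1202 and 1111 with total counts). The inducible chaperone gene hsp-70 stood at 60.3 CPM (56.5 to 64.3) against 1.66 (1.09 to 2.41), ugt-66 at 43.8 against 1.84, rmd-6 at 27.9 against 1.23, col-170 at 15.1 against 0.61 and ssp-19 had 212 counts against 3. Lower were ifas-1 with 0 counts against 190, nep-15 with 3 counts against 217, the lysozyme gene ilys-3 (log2 ratio -5.45), the lectin gene clec-70 (-5.28) and ech-9 (-4.49). The list medians went apart between these pairs. Collagens were at -2.62 (percentile 0) with ung-1 loss and 1.11 (percentile 100) with nth-1 loss, and muscle genes at -0.79 and 1.16, while cytosolic heat shock was at 0.44 and 0.83 (percentile 99.99 for each). Across 8919 genes, which are not independent replicates, the log2 ratios of the 2 pairs had r = -0.25 and rho = -0.12, in a family of 12 such relations. Scaling by total counts moved the median of all genes by -0.24 and -0.23 in these pairs.

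Genes picked in one set were then read in libraries of the other, so that picking and reading shared no library. The readings within a set did share libraries and are not independent results. The aggregate library on wild type enters aggregate over wild type and glycosylase loss in the aggregate strain with opposite signs. The wild type enters each reading taken over wild type. The 1684 genes higher with aggregate tau at 20 °C had a median log2 ratio of 1.44 at 22 °C (percentile 100, 96.3% of the genes higher). They also had medians of 0.53 for anti-aggregate tau (percentile 100, 79.7% higher) and 0.39 for the ung-1 library over wild type (percentile 100, 81.3% higher), and of -0.98 for ung-1 loss in the aggregate strain (percentile 0). Their median for aggregate tau on ung-1 was 0.18 (percentile 100), and 0.046 for the genes picked and read with total counts. The 1218 genes higher with aggregate tau at 22 °C had medians of 1.95 at 20 °C (percentile 100), of 0.12 for aggregate tau on nth-1 (percentile 100) and of 1.56 for the nth-1 library over wild type (percentile 100). They had medians of -0.04 for anti-aggregate tau (percentile 0) and of -0.21 for nth-1 loss in the aggregate strain (percentile 0). This last value became positive, at 0.19, without the genes called on wild-type backgrounds, and 0.08 with a size rule of 0.58. The 34 genes lower with aggregate tau at 20 °C had medians of -0.79 at 22 °C (percentile 0) and 0.59 for ung-1 loss in the aggregate strain (percentile 100). The 90 genes lower at 22 °C had medians of -0.44 at 20 °C (percentile 0) and -0.66 for nth-1 loss in the aggregate strain (percentile 0). The latter genes thus lay lower still with nth-1 loss. Across the 8919 genes, the aggregate over wild-type ratios of the 2 temperatures had r = 0.81 and rho = 0.80. Some other pairs without a shared library also correlated: aggregate tau at 22 °C and the nth-1 library, each over wild type, had r = 0.73 and rho = 0.63, aggregate tau at 20 °C and the ung-1 library r = 0.52 and rho = 0.52, and the ung-1 and nth-1 libraries r = 0.681 and rho = 0.575. Aggregate tau on ung-1 had r = -0.33 and rho = 0.08 with aggregate tau on wild type at 22 °C, and r = -0.06 and rho = 0.105 with that at 20 °C. For aggregate tau on nth-1 these values were r = 0.35 and rho = 0.47, and r = 0.41 and rho = 0.46. The anti-aggregate over wild-type ratios of the 2 temperatures had r = -0.61 and rho = -0.13.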

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

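The tests of explanations given here were chosen only after the results they bear on were seen, while the interaction test itself was planned. The effect of aggregate tau differed between wild-type and glycosylase-mutant backgrounds for Y73B3A.18, by a log2 difference of -5.91 (SE 0.36), and for odc-1, by -4.95 (SE 0.32), both with an edgeR quasi-likelihood adjusted p of 0.00693. On wild-type backgrounds their aggregate effects were 5.81 and 4.88. For odc-1 the adjusted p of the interaction ran from 8.09e-42 to 0.172 over 19 alternatives and passed in 11.

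Low smg-3 and a pseudogene-rich set of higher genes marked both aggregate libraries on a wild-type background and neither mutant aggregate library. A swap with libraries of a glycosylase mutant is argued against, because ung-1 stood at 41.2 CPM in the 22 °C aggregate library against at most 14.4 CPM in the ung-1 libraries, and nth-1 at 23.9 CPM in that of 20 °C against at most 11.2 CPM in the nth-1 libraries. The change of composition seen in the nth-1 libraries, with more collagen, muscle and sperm RNA, stays open. It was read in 388 of the 633 pseudogenes tested, those with a mean of at least 1 CPM. Their median log2 ratios over wild type were 0.19 in nth-1, 0.33 in nth-1 with aggregate tau and 2.19 in the aggregate pair of 20 °C. Random lists matched on mean expression gave 1.16 to 1.58, 1.30 to 1.75 and 1.1 to 1.41. That placement cannot decide, because the aggregate libraries raise the mean behind the cut-off and the matching. Pseudogenes were also chosen after their rise was seen. Summed over all annotated pseudogenes, the wild type of 20 °C held 3444 CPM and the aggregate library 10412. The nth-1 library held 4571 CPM and nth-1 with aggregate tau 5069, a smaller rise. Reduced nonsense-mediated decay in the aggregate stock remains a candidate explanation, with pseudogene medians of 2.35 at 22 °C and of 0.06 and 0.15 on the mutant backgrounds, the latter still at percentile 97.9; of decay targets listed before their values were seen, rsp-6 stood at 0.33 and 0.05, rsp-2 at 0.29 and -0.13 and rsp-4 at -0.22 and -0.50 in the 2 pairs, while rpl-3, rpl-7A, rpl-12 and tos-1, listed after, were higher in both. Other changes of composition or in the tau aggregate stock, an exchange among libraries on a wild-type background, and an effect of glycosylase loss on worms with aggregating tau, the biological difference the design names, were not tested.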

How the results depend on the processing

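The contrasts on wild-type backgrounds, taken from the interaction fit of all 12 libraries, were chosen after the data were seen. So were the fits without the 3 nth-1 libraries and the readings without the genes called on wild-type backgrounds, while the rest were planned. With 1 library per group the spread comes from the fit, a left-out library leaves its group to be predicted from the others, and depth limits single-library counts near the CPM floor. The fits compared tau states within each background as a block, and a block by replicate number does not apply with 1 library per group. Among named genes 1468 results kept their direction and side of the threshold, 127 passed it only under an alternative, 96 no longer passed it and 0 turned direction. This tally does not measure robustness. Where a comparison had matched pairs, its named genes had been chosen for moving the same way in each pair. Many of the named genes had not passed in the main fit and so could keep their side easily. Unless a cause is given, the cause was not tested.

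DESeq2 called 57 genes for aggregate against no tau, 1 for anti-aggregate against no tau, 1153 for aggregate against anti-aggregate, 5 for ung-1, 4210 for nth-1, 74 for their difference, 125 for the 22 °C against the 20 °C set, 648 within the aggregate strain, 385 for the interaction and 3304 for aggregate tau on wild-type backgrounds. By voom the counts were 1386 for nth-1, 295 within the aggregate strain, 28 for the interaction and 778 on wild-type backgrounds. The 20 °C libraries alone gave 59, 1489 and 4507 for the 3 contrasts of tau states and 3463 for nth-1, and the 22 °C libraries alone 0 for each tau contrast and for ung-1. The contrasts on wild-type backgrounds within the interaction fit gave 230, 1 and 149 for the tau states. A filter of 1 CPM in 6 libraries gave 1674 for nth-1, 307 within the aggregate strain and 47 for the interaction, no filter gave 24 for the interaction, and the model without a term for set by glycosylase gave 6. Without the 3 nth-1 libraries the counts were 1 for aggregate against no tau, 2 for the sets, 131 for the interaction and 3616 on wild-type backgrounds.

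Leaving out 1 library at a time gave 0 to 0 genes for each tau contrast and for ung-1, 0 to 5318 for nth-1, 0 to 953 for the difference, 0 to 2 for the sets, 0 to 478 within the aggregate strain, 0 to 163 for the interaction and 1 to 5671 on wild-type backgrounds. The highest counts came without the library labelled nth-1 with anti-aggregate tau for nth-1, the difference and the sets, and without ung-1 with anti-aggregate tau within the aggregate strain, for the interaction and on wild-type backgrounds.

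Of the lists passed by camera (24, 13 and 23 for the tau contrasts, 8 for ung-1, 23 for nth-1, 19 for their difference, 18 for the sets, 15 within the aggregate strain and 25 for the interaction), 0 passed with an estimated correlation in each, and fry passed 2 for nth-1, 1 for the sets and 0 for the others.

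For single libraries a floor of 20 CPM in place of 10 lowered the counts, by construction, to 804 and 1044 for aggregate over wild type at 22 °C and 20 °C, 305 for aggregate on ung-1, 307 for anti-aggregate at 22 °C, 90 for anti-aggregate on ung-1, 1562 for the library labelled nth-1 with anti-aggregate tau over nth-1 and 175 over anti-aggregate, 120 for ung-1, 802 for ung-1 in the aggregate strain and 145 in the anti-aggregate strain, 747 and 1007 for aggregate over anti-aggregate, 138 for the same on ung-1 and 226 between the wild types. A floor of 5 CPM raised them to 66 for aggregate on nth-1, 780 and 84 for anti-aggregate at 22 °C and 20 °C, 218 for anti-aggregate on ung-1, 299 for ung-1, 365 for ung-1 in the anti-aggregate strain, 468 for the library labelled nth-1 with anti-aggregate tau over anti-aggregate, 2509 for aggregate over anti-aggregate at 20 °C, 365 for the same on ung-1 and 609 between the wild types.

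Genes picked as higher at 20 °C and read at 22 °C had medians of 1.08 and 1.95 in aggregate over wild type with size rules of 0.58 and 1.5, and 1.26 without the genes called on wild-type backgrounds. In ung-1 loss within the aggregate strain the medians were -0.61 and -1.46 with those size rules, -1.18 with total counts and -0.74 without the called genes, and for aggregate on ung-1 0.11 with the rule of 1.5 and 0.046 with total counts. Genes picked at 22 °C and read at 20 °C had medians of 1.60 and 2.28 in aggregate over wild type, 1.88 with total counts and 1.81 without the called genes. For nth-1 loss within the aggregate strain they turned positive, at 0.084 with the rule of 0.58 and 0.19 without the called genes, and were -0.61 with the rule of 1.5. With aggregate on nth-1 the median was 0.11 with total counts. Genes picked as lower at 20 °C turned to -0.14 for ung-1 loss within the aggregate strain with the rule of 1.5, which left few genes.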

Other observations

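The tests of explanations given here, and the counts over other splits by unadjusted p, were chosen only after the results were seen, while the fits behind the fold changes were planned. Besides odc-1, the S-adenosylmethionine decarboxylase gene smd-1, of the same polyamine pathway, stood at 647 and 571 CPM in the 2 aggregate libraries on a wild-type background and at 59.5 to 296.5 CPM in the other 10 (log2 fold change on wild-type backgrounds 3.0, SE 0.31, edgeR quasi-likelihood adjusted p = 0.0126). The decay kinase gene smg-1 stood at 269 and 258 CPM against 121 to 173 CPM in the other 10, without passing (log2 fold change 0.93, SE 0.19, adjusted p = 0.072). Myosin heavy chain, from unc-54, reached 3911 CPM in the nth-1 library and 4081 CPM in nth-1 with aggregate tau, against 338 CPM in the wild type of 20 °C and 674 CPM in the library labelled nth-1 with anti-aggregate tau. These genes were chosen after their values were seen.

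The library labelled nth-1 with anti-aggregate tau lay nearer to the wild type than the other nth-1 libraries did. A mix of mutant and wild-type worms stays open: the nth-1 level would need 70.5% mutant worms (counting interval 63 to 77.3%) and the 3584 genes that differed between nth-1 and wild type gave a median share of 15.1%, but those genes may follow stage in place of genotype. Younger worms in the other nth-1 libraries stay open, because vitellogenins, whose mRNA rises at adulthood, went both ways over wild type, from -0.14 to 0.75 in nth-1 (median 0.14) and from -0.41 to 0.81 in nth-1 with aggregate tau (median 0.04). Sperm development genes had a median of 4.67 and oocyte and eggshell genes of -0.65 in nth-1 over wild type. An effect of anti-aggregate tau on nth-1 mutants, and a different genotype in that culture, were not tested and stay open with 1 library.

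Collagen, muscle and sperm genes were higher and germline genes lower in the aggregate libraries on a wild-type background. A lower share of germline alone would raise the lists of other tissues alike. The collagen median lay above that of the intestine list by 2.46 at 22 °C (1.91 to 3.01 over resampled members) and 2.02 at 20 °C (1.56 to 2.52). Intestine was picked as the lowest of the 6 other tissue lists, and the intervals do not allow for that choice. Against the nearest list the gaps were 1.17 (0.66 to 2.38) and 0.87 (0.335 to 1.32). Collagens thus lay above each of the 6 lists in both pairs, though their gap to the nearest was no larger than the largest gaps among those lists. These gaps argue against a lower share of germline as the only cause for the collagens. It may still be part of their rise, and the intervals cover the spread over members, not over libraries. For those 6 lists a lower share of germline alone stays open, because the highest and the lowest list were picked. Hypodermis lay 1.29 above intestine at 22 °C (0.18 to 1.63) and neuropeptides 1.15 above it at 20 °C (0.76 to 1.68). Younger worms are in line with the vitellogenin median of -1.47 at 22 °C (lower quartile -2.02) and stay open at 20 °C, where it was 0.02 and the members went both ways, from -0.41 to 0.80. A biological effect of aggregate tau on these tissues stays open, as does any cause shared by the 2 aggregate libraries.

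By the number of genes at an unadjusted p under 0.05 in the edgeR quasi-likelihood test, other splits of the libraries left chance open. With the real split included, as many genes as its 1874 for aggregate against no tau came from 3 of 35 splits (highest other 9188), as many as 253 for anti-aggregate against no tau from 16 of 35 (highest other 7338) and as many as 5047 for aggregate against anti-aggregate from 3 of 35 (highest other 7645). For the difference between the mutants 6 of 40 drawn splits gave as many as 2806 (highest other 5463). Among the 8 splits with 1 library of each background on either side, too few for a share under 0.05, as many came from 1, the real one, for aggregate against no tau (highest other 1394), from 5 with the real one for anti-aggregate against no tau (highest other 1182) and from 2 with it for aggregate against anti-aggregate (highest other 5584). The number of genes by adjusted p decides nothing here, since the real 0 is reached by each of the 35 or 40 splits. The highest other numbers by adjusted p, 8061, 4915 and 4225 for the tau contrasts and 102 for the difference, point to a structure of the samples. The split with 8061 differed from the real one only by exchanging nth-1 with ung-1 with aggregate tau, and that with 4225 only by exchanging ung-1 with aggregate tau with the anti-aggregate library of 22 °C. For ung-1, nth-1 and the sets, 10 splits of 3 against 3 are too few for a share under 0.05; the real number was 0 for each, and the highest other was 0, 4203 and 0.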
